A study of Mus musculus with 12 samples.

How the data were processed

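CD8+ T cells were sorted, after enrichment on CD45, from MC38 tumours in C57BL/6J mice. MC38 is a mouse colon carcinoma line that grows in mice of this background. Per the labels' protocols, radiotherapy of 20 Gy began when tumours measured 40 to 100 mm3, and sorted cells were lysed at 1000 to 5000 cells per microlitre. The lysates were read with a NanoString nCounter panel of mouse genes for immune exhaustion, which counts barcoded probes on single RNA molecules without amplification. There were 12 samples in 4 groups of 3, named Nontreated, SRT, CRT and SRT-like. The abbreviations of the radiotherapy modes are not spelled out in the labels and are used here as they stand. The labels do not say whether the samples of a group came from separate mice. They give each sample a number, which no samples of different groups share, and no batch.

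The deposited values are log2 values that the authors normalized in ROSALIND, per the labels. The version, the background handling and the probes that set each sample's factor are not given in the sources used here, and the table holds no control or reference probes. It holds 773 probes, with values from -0.68 to 13.92. Within each sample, 2 raised to the deposited value was a whole multiple of 1 step for 100% of the values. The molecule counts before scaling could therefore be recovered, and they gave the depth of each sample. Counts of few molecules carry most of the counting error, so low probes of shallow samples are the least precise.

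Background was estimated here from 26 panel probes for genes of other tissues, such as liver and pituitary, or for a virus. They were picked by known tissue, after the group comparisons had been seen. A probe was above background in a sample when it exceeded their mean plus 2 SD, and 482 probes were so in every sample of at least 1 group. Probes below that level stayed in the tests and are named as such. Of the probe names, 756 matched a symbol in the RefSeq gene table of GRCm38.p6. That table served for names only, and no coordinates are printed because the probes' target positions were not used here. A probe named for a pair of genes, such as Ifit3/3b, cannot tell them apart, and granzyme or MHC class I probes could also take up RNA of close relatives.

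The main test was limma (3.58.1, in R 4.3.3), with lmFit and eBayes without a trend, on the deposited log2 values of all 12 samples with 4 group means. It was 2-sided, with Benjamini-Hochberg adjustment over the 773 probes and a threshold of 0.05 on the adjusted p. There were 7 contrasts, each mode against Nontreated, each pair of modes, and the mean of the 3 modes against Nontreated, plus an F test over the 4 groups. With 3 samples per group, p-values measure only the spread between these samples, which may be technical. On simulated data for CRT against Nontreated (773 probes, 200 of them changed, 20 draws), the test recovered 80% of increases and 73.3% of decreases of 1 log2 unit. At 2 log2 units it recovered 97.2% and 96.4%, and 4.75% of the calls were false. Simulated data with no change gave a mean of 0.8 calls over the 7 contrasts. The changed probes were drawn only from those with a mean log2 value above 5, and the simulated noise was independent between probes. A draw called a mean of 182.1 probes, against 24 in the real CRT contrast. Real probes can vary together and fewer of them may change, so these rates need not hold for the real data.

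Gene lists were written before the data were examined, as were the groups, the tests and most of the other settings tried. Of 26 lists, 22 had at least 5 measured members and were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a contrast. The lists cover inhibitory receptors and exhaustion regulators, stem-like and memory genes, effector and cytotoxic genes, co-stimulation, T cell receptor signalling, cell cycle, p53 and DNA damage, and apoptosis. Others cover type I interferon response, MHC class I and antigen processing, NF-kB and AP-1, residency and adhesion, chemokine receptors, PI3K and mTOR, TGF-beta, and common gamma chain and JAK-STAT signalling. Other cell types are covered by lists for macrophages and monocytes, dendritic and antigen-presenting cells, B and plasma cells, CD4 and regulatory T cells, natural killer cells, and tumour and stroma. The 4 lists with too few measured members were left out. Each list was also tested with a correlation estimated from the data and with fry, which asks whether a list moves one way and compares it with no other genes.

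Genes were named by a fixed rule. For each contrast these were the 12 largest increases and the 12 largest decreases among probes past the threshold whose groups did not overlap. Where fewer than 5 passed, the 5 probes with the smallest unadjusted p were named too. Up to 4 members per list were taken by smallest p, and 12 genes of T cell function were fixed for every contrast. Of these 12, 9 were measured, and Mki67, Cdkn1a and Isg15 were not on the panel. Some genes that this rule names are not reported here.

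Other settings chosen then were median centring, quantile normalization, a floor of 5 on the mean log2 value, removal of the lowest 25% of probes, a trended robust prior, sample weights, fits on only the 6 samples compared, the 9 irradiated samples as 1 group, and leaving out each sample in turn. Settings chosen after the data were seen were limma's voom on the recovered counts, background subtraction, only probes above background, the scale step as a covariate, and a block for the run of sample numbers. The block divided samples 1 to 5 from 6 to 9. Samples 10 to 12, all SRT-like, formed a further run and were not in that fit. These runs were chosen here, since the labels give no batch. A scaling on reference genes was not run, because 0 of the 42 listed genes were measured. A count model and pseudocounts were not run either, since the values are deposited as logs. Other splits of the samples were counted, 10 for each pair of groups and 100 for the 12 samples, the real split included each time. No sample was left out of the reported values.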

Results

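The expression of 773 immune genes was measured in CD8+ T cells sorted from MC38 tumours, to compare 3 modes of radiotherapy with each other and with no treatment. Each of the 4 groups held 3 samples. The recovered molecule counts ranged from 118694 to 467904 per sample. Nontreated replicates 1 to 3 had totals of 366987, 467904 and 118694, and SRT replicates 259964, 271874 and 161752. CRT replicates had 299512, 160373 and 160828, and SRT-like replicates 421066, 299545 and 267514. Replicates correlated across probes with Pearson's r of 0.953 to 0.983, where probes are not independent replicates. Pairs of the same group differed by more than counting noise, so none was treated as a repeat deposit of 1 library. This does not show whether they came from separate mice.

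The genes of CD8+ T cells were high in every sample. The mean of the Cd3 and Cd8 probes lay between 10.8 and 11.4 on the log2 scale, and Cd8a averaged 10.73 ± 0.18 (SD, n = 3) in Nontreated. Cd4, the B cell gene Ms4a1, and the monocyte genes Csf1r and Cd14 were above background in 0 of the 12 samples. Other members of the lists for those cells were above background in all 12, with Nontreated means of 7.73 ± 0.26 for Ighm, an immunoglobulin gene of B cells, and 6.97 ± 0.06 for Cd86, 6.15 ± 0.26 for Tyrobp and 5.76 ± 0.30 for Cd68 of the macrophage list (SD, n = 3). Transcripts of antigen-presenting cells were measurable: H2-Aa, an MHC class II chain, averaged 8.28 ± 0.54 in Nontreated, 8.56 ± 0.60 in SRT, 8.32 ± 1.33 in CRT and 7.40 ± 0.16 in SRT-like (SD, n = 3). In a principal component analysis the first component held 34.5% of the variance and the second 18.3%. Nontreated samples lay at -8.77, -6.06 and -3.89 on the first, and the irradiated samples between -2.53 and 5.81. Within SRT, the sample with the highest number lay apart from the other 2, at 5.58 against -2.53 and -1.67. In every group the sample with the highest number lay highest on this component, with -3.89 in Nontreated, 5.81 in CRT and 4.08 in SRT-like. It was also the shallowest of its group, except in CRT, where it had 160828 counts against 160373. Depth, sample number and treatment were not separated on this component. The scaling raised the background of shallow samples, so that the 26 background probes averaged 15.1 in Nontreated replicate 3 and 6.24 and 6.26 in the other Nontreated samples. The SRT values were 9.84, 12.4 and 14.2, the CRT values 9.90, 13.7 and 14.0, and the SRT-like values 8.28, 9.64 and 9.96. The median of all probes was also higher after radiotherapy, by 0.27 in SRT, 0.32 in CRT, 0.18 in SRT-like and 0.26 over the modes. The differences below include this shift.

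**Figure D1:**
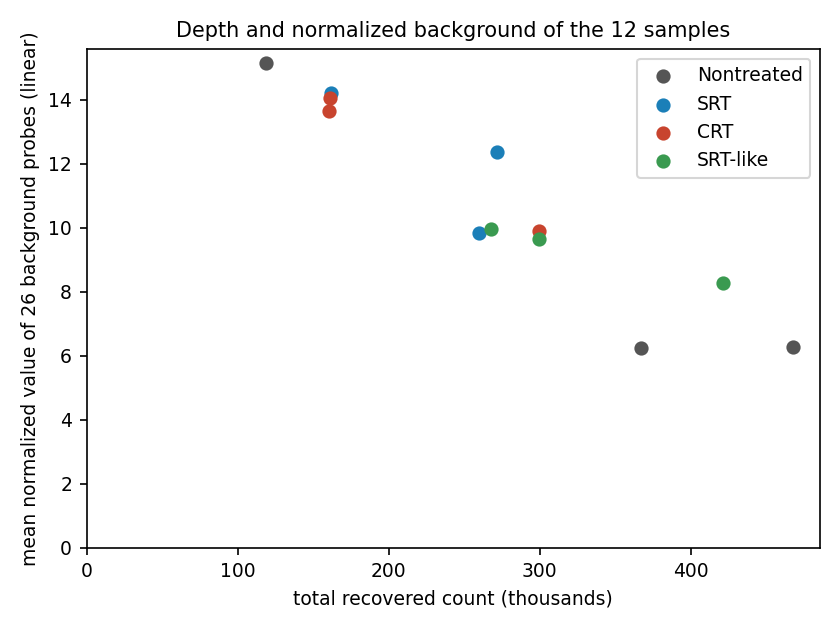
The horizontal axis gives the total recovered count of each sample, in units of 1000, and the vertical axis the mean normalized value of 26 background probes on a linear scale, with 1 point per sample coloured by group. The shallowest sample, Nontreated replicate 3 at 118694 counts, had the highest background, 15.1.

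Taking the 3 modes together, 9 genes induced by type I interferon were higher in all 9 irradiated samples than in any control. Rsad2, an antiviral enzyme, rose 4.22-fold (log2 difference 2.08 ± 0.28 SE, adjusted p = 0.0148), Mx2, an antiviral GTPase, 4.37-fold (2.13 ± 0.37) and Ifit3/3b 3.82-fold (1.93 ± 0.32). Rsad2 and Mx2 were above background in only 1 of the 3 Nontreated samples, so their folds are understated. Of the 11 measured members of the interferon list, 9 rose over all probes, among them Ifit1, Mx1, Oas1a, Oas2, Oas3 and Bst2, and 10 did so adjusted over the list alone. The exception was the chemokine Cxcl9, with a difference of -0.44 ± 0.39 and 2 of 3 samples of each group above background. The median of the list was 1.70, with an adjusted p of 1.27e-09 by camera, 0.332 with an estimated correlation and 0.00434 by fry. The interferon-inducible Xaf1 and Rnf213, outside that list, rose by 1.20 ± 0.23 and 0.99 ± 0.22, and were chosen after their values were seen.

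Genes of other lists rose with them. Cd80, a ligand of CD28 and CTLA-4 and a member of the dendritic cell list, rose 3.37-fold (1.75 ± 0.31, adjusted p = 0.0267), and the chemokine receptors Ccr1 and Cxcr3 rose by 1.31 ± 0.20 and 0.82 ± 0.18. Ccr1 was above background in 2 of the 3 Nontreated samples, as was Tnfsf9. Klf2, a factor of quiescent and recirculating T cells, rose by 1.14 ± 0.22. The co-stimulatory genes Tnfsf9, which encodes the 4-1BB ligand, and Cd226 rose by 0.87 ± 0.17 and 0.62 ± 0.14, as did Cd86, a list member for macrophages, by 0.66 ± 0.14. MHC class I and antigen processing genes shifted up as a list, with 9 of 9 members higher, a median of 0.40 and 0 members past the threshold over all probes or adjusted over the list alone (limma). That list had an adjusted p of 0.0155 by camera, 0.72 with an estimated correlation and 0.0107 by fry. The 9 fixed genes did not pass, with Gzmb at 0.86 ± 0.27 (adjusted p = 0.153), Tox at -0.45 ± 0.15, Tcf7 at 0.64 ± 0.27, Havcr2 at 0.21 ± 0.16, Ifng at 0.23 ± 0.29, Prf1 at 0.22 ± 0.19, Pdcd1 at -0.05 ± 0.20, Slamf6 at -0.04 ± 0.17 and Tnfrsf9 at -0.17 ± 0.16. The signs of Havcr2, Ifng, Pdcd1 and Prf1 turned under another scaling or weighting, and that of Slamf6 with 1 sample left out.

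By limma 24 probes rose and 0 fell for radiotherapy as a whole, 20 of the 24 above background. Among the 118 probes with an unadjusted p under 0.05, 111 were higher and 7 lower, and limma's voom on the recovered counts called 27. In 38 probes (4.92%) the 9 irradiated and 3 control samples did not overlap, where chance gives 0.909%. The count was 77 without Nontreated replicate 3, 4 without Nontreated replicate 1, 9 without Nontreated replicate 2, 2 without CRT replicate 2 or SRT-like replicate 2, 14 without CRT replicate 1 and 15 without SRT-like replicate 3. Median centring left 11 calls, quantile normalization 2, the 9 irradiated samples as 1 group 8, and sample weights gave 64.

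**Figure D2:**
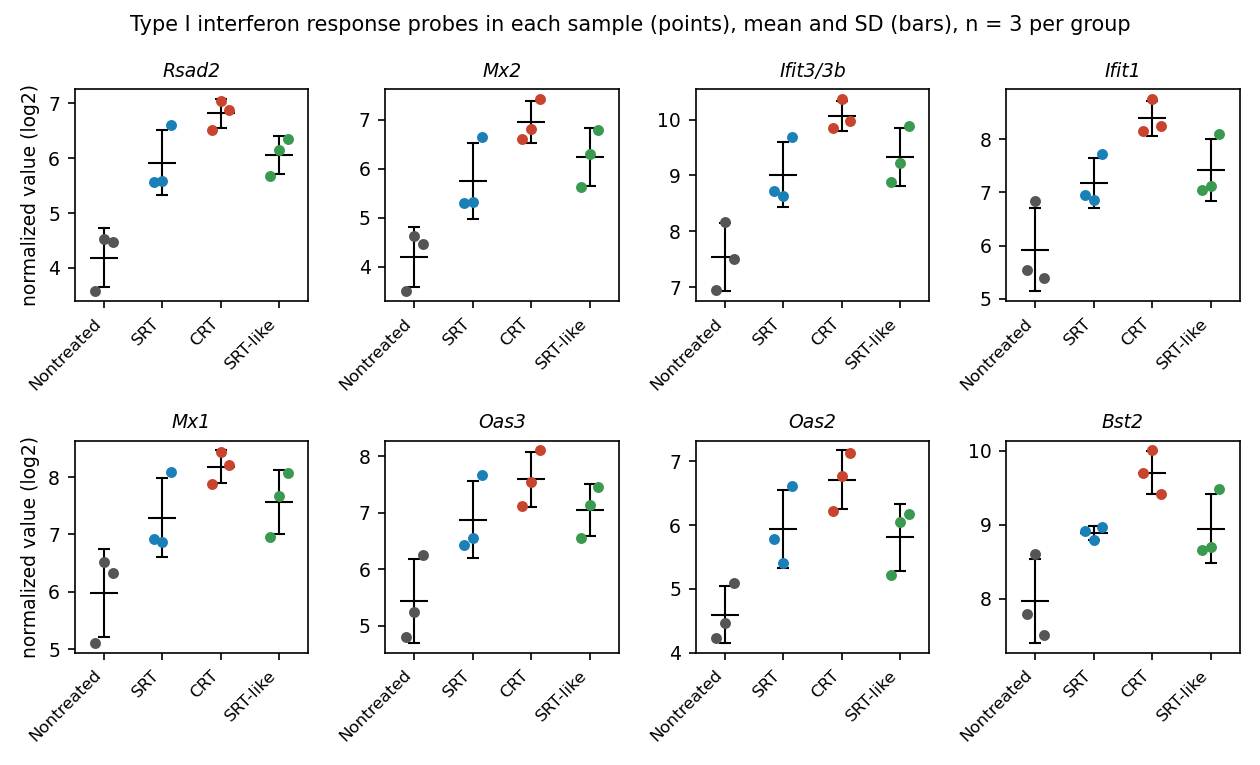
Each panel gives the normalized log2 value of 1 interferon-induced probe by group, with points for samples and bars for the mean ± SD (n = 3). Rsad2 averaged 4.19 in Nontreated, 5.92 in SRT, 6.82 in CRT and 6.06 in SRT-like, and Bst2 7.97, 8.89, 9.71 and 8.95.

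The other 20 lists did not pass by camera for radiotherapy as a whole. Median differences of T cell lists were 0.03 for inhibitory receptors, 0.24 for stem-like and memory genes, 0.24 for effector genes, 0.13 for co-stimulation, 0.09 for T cell receptor signalling and 0.18 for residency. Cell cycle genes had a median of 0.21, p53 and DNA damage genes 0.27, apoptosis genes 0.10, NF-kB and AP-1 genes 0.15 and chemokine receptors 0.44. The medians were -0.03 for PI3K and mTOR genes, 0.16 for TGF-beta and 0.03 for gamma chain signalling. Lists of other cells had medians of 0.44 for macrophages, 0.26 for dendritic cells and 0.57 for B cells. They were 0.09 for CD4 and regulatory T cells, 0.32 for natural killer cells and 0.32 for tumour and stroma. In these lists 7 of 12 macrophage, 7 of 10 B cell, 4 of 8 CD4 and 3 of 6 tumour and stroma members were not above background. The 26 background probes themselves had a median difference of 0.449. Relative to the whole panel, camera placed the inhibitory, T cell receptor, apoptosis, NF-kB, TGF-beta, gamma chain, CD4 and natural killer lists lower although their medians were above 0.

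In CRT against Nontreated, which asks what this mode changed, the interferon genes again led. Mx2 rose 6.80-fold (2.77 ± 0.46 SE, adjusted p = 0.0151), Rsad2 6.20-fold (2.63 ± 0.35, adjusted p = 0.011) and Ifit3/3b 5.78-fold (2.53 ± 0.39), with all 3 CRT samples above all 3 controls. Ifit3/3b averaged 7.54 ± 0.62 (SD, n = 3) in Nontreated and 10.07 ± 0.27 in CRT. Ifit1, Mx1, Oas3, Oas2, Oas1a, Xaf1 and Bst2 rose by 1.74 to 2.46. Of the interferon list 9 of 11 members rose over all probes and 10 adjusted over the list alone, with a median of 2.15 and an adjusted p of 7.35e-11 by camera. For this list adjusted p = 0.246 with an estimated correlation and 0.0022 by fry. With the run of sample numbers as a block, its median was 2.47 in CRT and 1.586 in SRT.

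Other genes that rose in CRT were Cxcr3, the receptor of interferon-induced chemokines (1.23 ± 0.22, adjusted p = 0.0162), Ccr1 (1.25 ± 0.24), Cd86 (0.98 ± 0.17), the checkpoint kinase gene Chek1 (0.74 ± 0.17) and the apoptosis gene Casp8 (0.74 ± 0.17). Ptpn6, which encodes the phosphatase SHP-1 that dampens T cell receptor signals, fell by 0.82 on the log2 scale (SE 0.19, adjusted p = 0.0447). Ido2 and Ccnb3 passed by 1.89 and 1.76 but were not above background. Cell cycle genes were higher in 7 of 7 members, with a median of 0.61, E2f2 at 0.88 ± 0.26 and Mcm5 at 0.65 ± 0.22. The list did not pass by camera (adjusted p = 0.0562) or with an estimated correlation (0.777), and passed by fry (0.026). Of its members 0 passed over all probes and 2 adjusted over the list alone. Gzmb (1.15 ± 0.33) and Tox (-0.67 ± 0.19) both had an adjusted p of 0.103, and Ccr7, a lymph node homing receptor, was at -1.08 ± 0.28 with 0.0772. Vsir was at 0.70 ± 0.17, Cd274 at 0.78 ± 0.24 and Cd69 at 1.32 ± 0.35. The other fixed genes had differences of -0.28 for Pdcd1, 0.37 for Havcr2, 0.25 for Ifng, 0.40 for Prf1, -0.16 for Slamf6, 0.39 for Tcf7 and -0.21 for Tnfrsf9, with the sign of Ifng turning under median centring. Lists of other cells did not pass by camera, with 11 of 12 macrophage genes higher (median 0.63), 1 of them, Cd86, past the threshold over all probes and 2 adjusted over the list alone. Of the B cell list 8 of 10 were higher (0.46), with 1 past the threshold over all probes and 1 adjusted over the list alone, Blk (1.25, not above background). Of the macrophage list 7 members were not above background, as were 7 of the B cell list. The 26 background probes averaged 3.46 in CRT against 2.89 in Nontreated (log2). Cd68 was at 0.65 ± 0.18 and Cd80 at 1.29 ± 0.38, neither past the threshold over all probes.

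The CRT contrast had 23 increases and 1 decrease, 20 of the 24 above background, and 119 probes with an unadjusted p under 0.05. Groups did not overlap in 136 probes (17.6%, where chance gives 10%). The count fell to 0 without CRT replicate 2, 6 without CRT replicate 3, 3 without Nontreated replicate 1 and 15 without Nontreated replicate 2, and was 58 without Nontreated replicate 3. It was 0 with only the 6 samples of these groups, 12 with median centring, 13 with quantile normalization (11 up) and 62 with sample weights.

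In SRT against Nontreated the interferon list shifted up as well, with 11 of 11 members higher, a median of 1.31 and an adjusted p of 6.62e-06 by camera. The list had adjusted p = 0.721 with an estimated correlation and 0.0655 by fry. Its members counted 0 over all probes and 9 adjusted over the list alone. Rsad2 had a difference of 1.74 ± 0.35 and Ifit3/3b of 1.47 ± 0.39. Of the stem-like and memory list, Klf2 was at 1.21 ± 0.27, Tcf7 at 0.97 ± 0.33 and Lef1 at 0.90 ± 0.29. That list did not pass, with 10 of 15 members higher, an adjusted p of 0.627 by camera and adjusted p = 0.82 with an estimated correlation. Its mean was 7.46, 7.51 and 8.13 in SRT replicates 1 to 3, against 7.42, 7.26 and 7.14 in the controls. The survival gene Bcl2 was at 1.73 ± 0.46, with 8.10, 8.12 and 9.62 in the SRT samples. None of these passed singly over all probes, nor did Ccr1 (1.22 ± 0.24), Cd80 (1.83 ± 0.38), Gzmd (1.20 ± 0.27) and Maml3 (1.14, not above background), at a smallest adjusted p of 0.15. Adjusted over the list alone, 2 stem-like, 3 co-stimulatory, 1 effector, 1 apoptosis and 1 chemokine receptor members passed. Cd70, above background in 2 of the 3 controls, was at 0.89 ± 0.23 and Cd226 at 0.62 ± 0.17. The other fixed genes did not pass either, with Gzmb at 0.61 ± 0.33, Havcr2 at -0.05, Ifng at 0.02, Pdcd1 at -0.18, Prf1 at 0.19, Slamf6 at 0.17, Tnfrsf9 at -0.22 and Tox at -0.34 ± 0.19, the last without overlap between the groups. Among these the signs of Havcr2, Ifng, Pdcd1, Prf1 and Slamf6 turned with another scaling, sample weights or 1 sample left out.

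Lists of other cells were higher in SRT too without passing by camera. Higher were 12 of 12 macrophage genes (median 0.48), 8 of 10 dendritic cell genes (0.48), 9 of 10 B cell genes (0.57) and 6 of 6 tumour and stroma genes (0.57). Adjusted over the list alone, 3 macrophage and 1 dendritic cell members passed. However, 7 macrophage, 1 dendritic cell, 7 B cell and 3 tumour and stroma members were not above background. The 26 background probes averaged 3.38 in SRT against 2.89 in Nontreated (log2), so part of these shifts may be background. For SRT limma called 0 probes, with 84 at an unadjusted p under 0.05 (80 higher, 4 lower), and voom called 2. A few were also called with the floor, a trended robust prior, only probes above background or the block, as given below. Without Nontreated replicate 1 there was 1 call, and groups did not overlap in 102 probes (13.2%, against 10% by chance).

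In SRT-like against Nontreated 5 probes rose, each with all 3 treated samples above all 3 controls and an adjusted p of 0.0421. No SRT-like sample shares a run of sample numbers with a control, so a batch along the numbers cannot be told apart from this mode. Cd80 rose 4.39-fold (2.13 ± 0.38 SE), Rsad2 by 1.87 ± 0.35, Klf2 by 1.46 ± 0.27, Ccr1 by 1.45 ± 0.24 and Tnfsf9 by 1.14 ± 0.21. The interferon list had a median of 1.50 and an adjusted p of 2.98e-07 by camera, 0.292 with an estimated correlation and 0.016 by fry. It had 1 member past the threshold over all probes and 9 adjusted over the list alone. Effector genes shifted up as a list, with 20 of 22 members higher and a median of 0.35. The adjusted p was 0.00714 by camera, 0.431 with an estimated correlation and 0.0297 by fry. Of the effector genes 0 passed over all probes by limma and 1 adjusted over the list alone. Examples were Gzmd at 1.20 ± 0.27 and Gzmf at 1.36 ± 0.43, granzymes of close sequence, and Tnf at 1.15 ± 0.36. MHC class I genes were higher in 9 of 9 members, with a median of 0.49. Their adjusted p was 0.00208 by camera, 0.292 with an estimated correlation and 0.016 by fry. Of these 0 passed over all probes and 3 adjusted over the list alone, with H2-T23 at 1.02 ± 0.34 and Psmb9 at 0.46 ± 0.15. Without Nontreated replicate 3 camera called only 1 list here, the interferon list, so the effector and MHC class I calls were lost.

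Further SRT-like values that did not pass were Mx2 (2.05 ± 0.46) and Ifit3/3b (1.79 ± 0.39), both with an adjusted p of 0.0846, Bcl2 (1.72 ± 0.46), Jun (1.50 ± 0.42), and the residency genes Zfp683 (1.30 ± 0.40), Cd69 (1.16 ± 0.35) and Itgae (1.05 ± 0.50). Lists of other cells did not pass and went both ways, with 8 of 12 macrophage genes, 4 of 10 dendritic cell genes, 8 of 10 B cell genes and 5 of 6 tumour and stroma genes higher. Their medians were 0.23, -0.34, 0.36 and 0.24, and 7, 1, 7 and 3 of their members were not above background. The 26 background probes averaged 3.05 in SRT-like against 2.89 in Nontreated (log2). Single members with negative values were Siglech at -1.20 ± 0.44, a bound because 1 of 3 SRT-like samples was above background, H2-Aa at -0.88 ± 0.57 and Tyrobp at -0.76 ± 0.39. The fixed genes had 0.83 for Gzmb, 0.32 for Havcr2, 0.41 for Ifng, 0.30 for Pdcd1, 0.06 for Prf1, -0.12 for Slamf6, 0.57 for Tcf7, -0.09 for Tnfrsf9 and -0.35 for Tox. Prf1 turned under another scaling, and Slamf6 and Tnfrsf9 with 1 sample left out. There were 86 probes with an unadjusted p under 0.05 (80 higher, 6 lower), and 126 without overlap (16.3%, against 10% by chance). The call count was 0 without each of Nontreated replicates 2 and 3, SRT replicates 1 and 2, SRT-like replicates 2 and 3 and the 3 CRT samples in turn. It was 3 without Nontreated replicate 1, 1 without SRT-like replicate 1, 9 without SRT replicate 3, 0 under median centring, quantile normalization, background subtraction or a fit on the 6 samples alone, 13 with the scale step as a covariate and 15 with sample weights or voom.

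**Figure D3:**
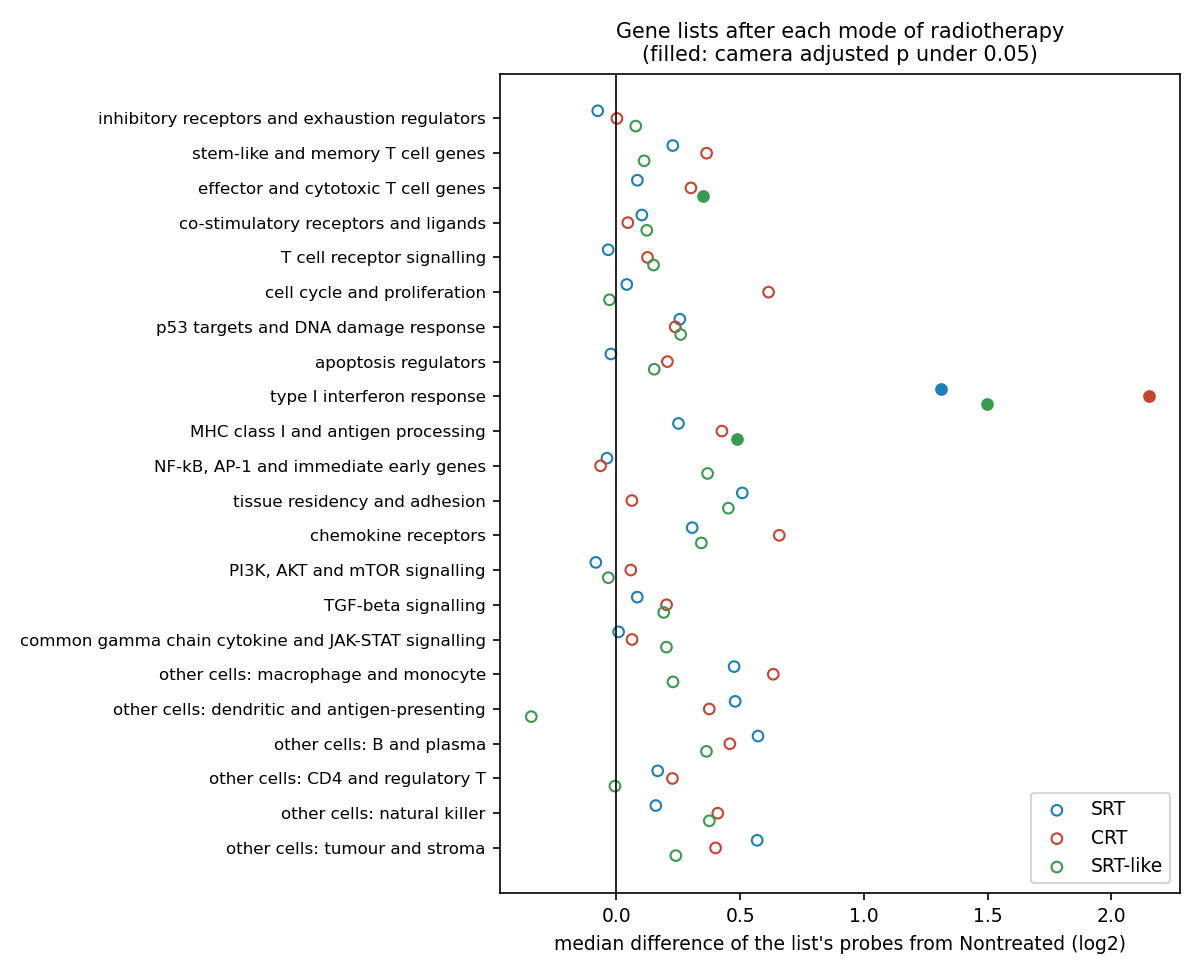
Points give the median log2 difference from Nontreated of each gene list (horizontal axis) for SRT, CRT and SRT-like (colours), filled where camera gave an adjusted p under 0.05. The interferon list stands at 1.31, 2.15 and 1.50, and the filled points besides are the effector (0.35) and MHC class I (0.49) lists in SRT-like.

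The 3 modes were compared by their differences from the shared controls, across probes. Pearson's r was 0.672 for SRT and CRT, 0.579 for SRT and SRT-like and 0.525 for CRT and SRT-like, where genes are not independent replicates. Unchanged groups sharing 3 controls were simulated by drawing samples at random from the residuals of all 12. They gave a mean of 0.479 (central 95% of 1000 draws -0.081 to 0.833). The covariances of 0.141, 0.109 and 0.112 exceeded the simulated mean of 0.0772 by 0.0633, 0.032 and 0.0349. All lay within the simulated limits, taken in the same way, of -0.0098 to 0.188. The same sign was shared by 76.8%, 73.1% and 70.1% of probes. CRT and SRT-like shared 2 called increases, Rsad2 and Ccr1, where independent lists would share 0.15. The controls were not split, since a part would have held 1 sample, so part of any excess may come from the shared controls.

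Between SRT and CRT no single gene differed past the threshold. The probes with the smallest p were Ccr7 (1.15 ± 0.28 higher in SRT), the integrin gene Itgae (1.69 ± 0.50, with 1 of 3 CRT samples above background), the aryl hydrocarbon receptor Ahr (0.60 ± 0.17), Gzmd (0.87 ± 0.27) and the oxidative stress factor Nfe2l2 (-0.59 ± 0.18), all with an adjusted p of 0.564. The interferon list was lower in SRT, with a median of -0.81, an adjusted p of 2.33e-05 by camera and adjusted p = 0.572 with an estimated correlation, and Ifit1 at -1.22 ± 0.42. Cell cycle genes were lower in 7 of 7 members, with a median of -0.49, an adjusted p of 0.00238 by camera and adjusted p = 0.572 with an estimated correlation, and E2f2 at -0.75 ± 0.26. Both lists had 0 members past the threshold over all probes and adjusted over the list alone by limma. Without SRT replicate 3 camera called only 1 list here, the interferon list, so the cell cycle call was lost. The fixed genes were at -0.54 for Gzmb, -0.41 for Havcr2, -0.22 for Ifng, 0.10 for Pdcd1, -0.21 for Prf1, 0.33 for Slamf6, 0.58 for Tcf7, -0.01 for Tnfrsf9 and 0.32 for Tox. Among them the signs of Ifng and Tnfrsf9 turned under another scaling or with 1 sample left out, and those of Pdcd1 and Prf1 with 1 sample left out. Limma and voom called 0 probes, with 51 at an unadjusted p under 0.05, and 88 did not overlap (11.4%, against 10% by chance).

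Between SRT and SRT-like the probe with the smallest p was for the chemokine gene Ccl22, a product of activated dendritic cells (2.31 ± 0.51 higher in SRT, adjusted p = 0.718). Ccl5, a chemokine of effector T cells, was at -0.76 ± 0.22, with Vav2 at 0.92 ± 0.28 and Slc8a1, not above background, at 1.44 ± 0.44 (adjusted p = 0.838). Ccl22 and Vav2 were above background in only 1 of the 3 SRT-like samples, so their differences are bounds and not exact sizes. Camera called 10 lists. T cell lists were lower in SRT, such as effector genes (median -0.25, adjusted p = 0.000165, 20 of 22 lower) and NF-kB and AP-1 genes (-0.35, 0.000165, 11 of 11 lower). Lists of dendritic cells (0.76) and macrophages (0.46) were higher in SRT, with H2-Aa at 1.15 ± 0.57 and Tyrobp at 0.87 ± 0.39. SRT samples carry the numbers 2, 3 and 8 and SRT-like samples 10 to 12. The MHC class II means of these SRT samples were 6.49, 7.188 and 6.239. Mode and a batch along the sample numbers cannot be told apart in this comparison. Of the macrophage list 7 of 12 members were not above background. The 26 background probes averaged 3.38 in SRT against 3.05 in SRT-like (log2). With an estimated correlation 0 of the 10 passed, with adjusted p from 0.411 to 0.495. The fixed genes were at -0.22 for Gzmb, -0.37 for Havcr2, -0.39 for Ifng, -0.47 for Pdcd1, 0.13 for Prf1, 0.29 for Slamf6, 0.40 for Tcf7, -0.13 for Tnfrsf9 and 0.01 for Tox, and the signs of Prf1, Tnfrsf9 and Tox turned with another scaling, sample weights or 1 sample left out. Limma and voom called 0 probes, with 44 at an unadjusted p under 0.05, and 81 did not overlap (10.5%, against 10% by chance). The count of lists was 4 without SRT-like replicate 1, 6 without SRT replicate 1 and 5 without SRT replicate 2.

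Between SRT-like and CRT the probes with the smallest p included the residency genes Itgae and Zfp683 and, of the stem-like list, Xcl1. Itgae, which encodes the integrin CD103, had a difference of 2.19 ± 0.50, with 7.01 ± 0.25 (SD, n = 3) in SRT-like and 4.82 ± 0.95 in CRT. Zfp683, which encodes the residency factor Hobit, had 1.83 ± 0.40, and the chemokine gene Xcl1 1.13 ± 0.28, each with no overlap between groups and an adjusted p of 0.369. Itgae and Zfp683 were above background in only 1 of the 3 CRT samples, so their differences from CRT are bounds and not exact sizes. The residency list had 4 members higher and 3 lower, with a median of 0.29 and an adjusted p of 0.00573 by camera, with adjusted p = 0.192 with an estimated correlation. Of this list 0 members passed over all probes by limma and 2 adjusted over the list alone. Cell cycle genes were lower in SRT-like in 7 of 7 members (median -0.66, adjusted p = 0.000229 by camera), with adjusted p = 0.192 with an estimated correlation and 0.0422 by fry. Their 4 members lower adjusted over the list alone were E2f2 (-0.86 ± 0.26), Mcm5 (-0.67 ± 0.22), Cdc25a (-0.66 ± 0.21) and Ccnb1 (-1.02 ± 0.35), and 0 passed over all probes by limma.

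The interferon list was lower in SRT-like in 11 of 11 members, with a median of -0.74, an adjusted p of 0.00156 by camera and adjusted p = 0.505 with an estimated correlation. The macrophage list was lower in 12 of 12 members (median -0.51, adjusted p = 0.0194 by camera), with adjusted p = 0.505 with an estimated correlation. It had 0 members past the threshold over all probes or adjusted over the list alone by limma, and 7 were not above background. The 26 background probes averaged 3.05 in SRT-like against 3.46 in CRT (log2). Single genes of other cells, none of them past the threshold over all probes, included Siglech, a gene of plasmacytoid dendritic cells, at -1.60 ± 0.44. That value is a bound, with 1 of 3 SRT-like samples above background. Tyrobp was at -1.38 ± 0.39 and Blk, not above background, at -1.05. Adjusted over the list alone, 2 dendritic cell, 1 B cell and 1 natural killer members were lower and 1 natural killer member higher. The fixed genes were at -0.32 for Gzmb, -0.05 for Havcr2, 0.17 for Ifng, 0.57 for Pdcd1, -0.34 for Prf1, 0.04 for Slamf6, 0.18 for Tcf7, 0.13 for Tnfrsf9 and 0.31 for Tox. Havcr2 and Tnfrsf9 turned in sign under another scaling, and Havcr2, Ifng and Slamf6 with 1 sample left out. Limma and voom called 0 probes, with 76 at an unadjusted p under 0.05 (23 higher, 53 lower), and 143 did not overlap (18.5%, against 10% by chance). Without Nontreated replicate 2 there was 1 call. SRT-like and CRT share no run of sample numbers, so mode and a batch along the numbers cannot be told apart here either.

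**Figure D4:**
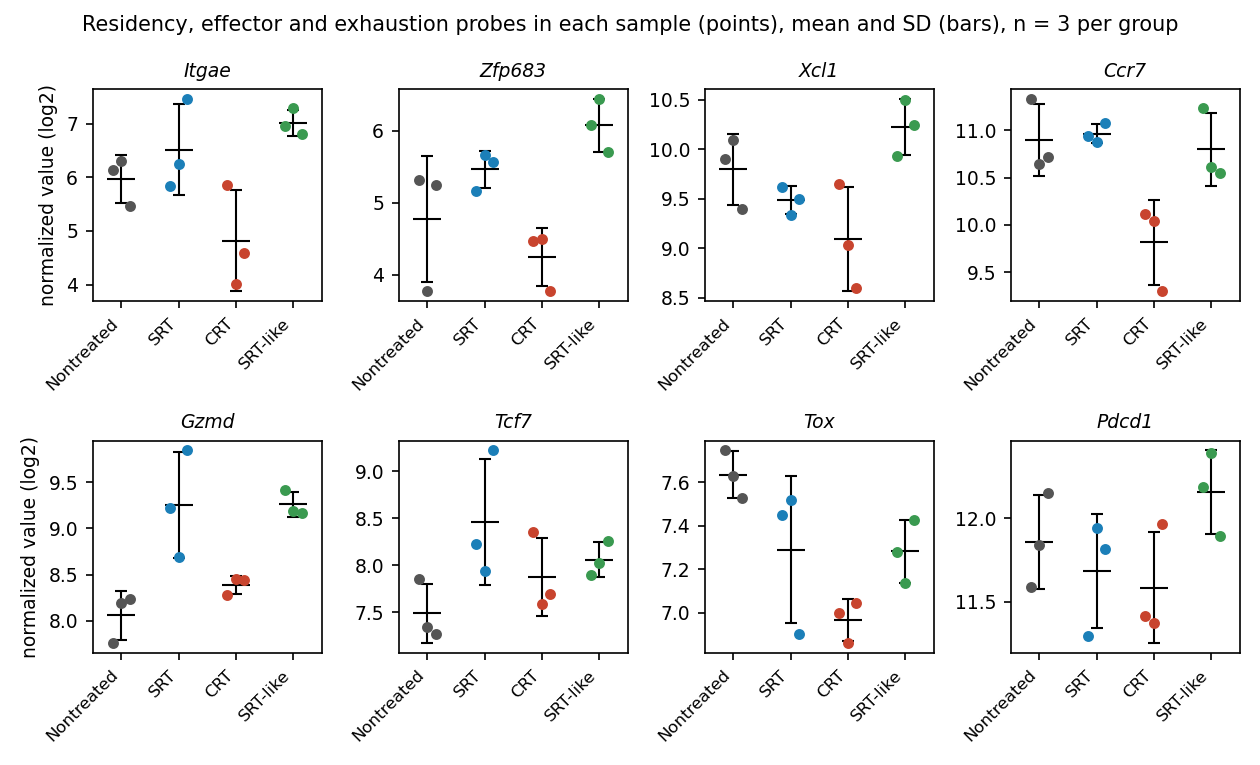
Each panel gives the normalized log2 value of 1 probe for residency, effector or exhaustion genes by group, with points for samples and bars for the mean ± SD (n = 3). Itgae averaged 5.97 in Nontreated, 6.51 in SRT, 4.82 in CRT and 7.01 in SRT-like, while Pdcd1 averaged 11.86, 11.68, 11.58 and 12.16.

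Over the 4 groups at once, limma's F test called 0 probes at a smallest adjusted p of 0.0818, with 92 at an unadjusted p under 0.05, and voom called 25. The count was 25 with the floor on low values, 16 without the lowest 25% of probes, 23 with a trended robust prior, 11 with sample weights and 19 with only probes above background. Without Nontreated replicate 1 it was 1, and without SRT replicate 3 it was 6.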

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

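The counts of other splits and the tests of explanations in this part were all specified after the results were seen, while the list tests between modes were planned.

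The following differences between modes passed by camera and did not pass with an estimated correlation. SRT was below CRT in the cell cycle list (median log2 difference -0.487) and the interferon list (-0.814). SRT was below SRT-like in inhibitory receptors and exhaustion regulators (-0.207), effector genes (-0.246), T cell receptor signalling (-0.145), MHC class I (-0.151), NF-kB and AP-1 (-0.346), residency (-0.501) and gamma chain signalling (-0.211). It was above SRT-like in macrophage (0.46), dendritic cell (0.762) and B cell (0.327) genes. Of these lists 7 of 12 macrophage, 1 of 10 dendritic cell and 7 of 10 B cell members were not above background. The 26 background probes averaged 3.38 in SRT, 3.46 in CRT and 3.05 in SRT-like (log2). Part of the macrophage and B cell differences between modes may therefore be background. The SRT-like samples share no run of sample numbers with SRT or CRT. In comparisons with SRT-like, mode and a batch along the numbers cannot be told apart. SRT-like was below CRT in the cell cycle list (-0.661), the interferon list (-0.737) and the macrophage list (-0.508). It was above CRT in NF-kB and AP-1 (0.276), residency (0.294) and gamma chain signalling (0.206), and by camera also in stem-like (0.065), effector (0.038) and T cell receptor (0.01) genes, whose medians lie near 0. By fry, only the cell cycle list between SRT-like and CRT passed (adjusted p = 0.0422).

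Other splits of the 12 samples into 9 and 3 were counted for radiotherapy as a whole. Of 100 splits, the real one included, 2 called at least the real 24, a share under 0.05. The other of these called 75, and this count was specified after the results. A division of the samples by something other than treatment is therefore not excluded. That split set Nontreated replicates 1 and 2 with SRT-like replicate 1 against the rest, and 23 of its 75 calls were above background, against 20 of 24 in the real split. A count this far above the real one points to a structure among the samples, whose cause was not tested. These 3 samples have the 3 highest totals and the 3 lowest backgrounds, and 2 of them are controls, so treatment is mixed into these calls. For lists, 59 of 100 splits called as many as the real 2 (highest other 10), so a random division is not excluded there. For the F test the real count was 0, which all 100 splits reach by construction (highest other 2), so nothing follows from it. For the interferon median, 1 of 100 splits, the real one, reached 1.698, with 1.318 as the highest other.

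With 3 samples against 3 there are 10 splits, too few for a share under 0.05. For probes, the real count, the number of splits as large and the highest other were 0, 10 and 54 in SRT against Nontreated, 24, 2 and 57 in CRT, and 5, 1 and 1 in SRT-like. The splits with 57 and 54 calls set Nontreated replicates 1 and 2 with CRT replicate 1 or SRT replicate 1, with 10 and 13 of those calls above background. Between modes the counts were 0 in the real and the other splits. A real count of 0, there and in SRT against Nontreated, is reached by 10 of 10 splits by construction and says nothing about chance. For lists, they were 1, 10 and 7 in SRT, 1, 9 and 9 in CRT, 3, 7 and 4 in SRT-like, 2, 7 and 3 in SRT against CRT, 10, 1 and 4 in SRT against SRT-like, and 9, 1 and 5 in SRT-like against CRT.

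Interferon genes were higher after radiotherapy by a median of 1.70. A lower amount of RNA or a larger scale factor is argued against, since the median was 1.522 with the scale step as a covariate. A batch that divides samples 1 to 5 from 6 to 9 is argued against in SRT and CRT, where the smaller median was 1.586 with this block. Other batches were not tested. The median SE of the single probes was 0.253 and 0.292 in these fits, which is not an SE of the list median. In SRT-like 0 samples share a run of numbers with a control, so batch and group cannot be told apart there. Carried-over antigen-presenting cells stay open: the interferon mean exceeded the MHC class II mean by 1.291 (SE 0.608, 95% interval -0.111 to 2.692). Another 2 forms of this test leaned against carry-over but cannot decide it. MHC class II had an upper limit of 1.19, against an interferon mean of 1.405 (SE 0.218), whose own error that form ignores. With MHC class II as a covariate the interferon median was 1.743 (median SE of the single probes 0.289). That covariate divides samples 1 to 5 from 6 to 12, so it cannot be told apart from the run of sample numbers. The form kept was chosen after all 3 were seen, as the most cautious. In SRT-like the MHC class II means were 5.635, 6.028 and 5.712, against 6.816, 6.019 and 5.601 in the controls. The interferon means were 7.091, 7.42 and 7.739 there, against 5.817, 6.507 and 6.306. MHC class II thus did not rise with the interferon genes in SRT-like, though Cd80 of the dendritic cell list did. Over the 12 samples the 2 means had r = -0.087. A response to radiotherapy may account for the rest.

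Most small p-values against Nontreated were increases, 94.1% of 118 for radiotherapy as a whole. Among probes near background this could be the scaling, since the 26 background probes had a median difference of 0.449, close to the 0.377 of all probes not above background. For probes above background, a background that rises with the scale factor is argued against as the whole cause. Of their small p-values 87% were increases with the scale step as a covariate and 92% without it. A shift of the whole panel was not tested as a cause. The median difference of these probes was 0.116 with the covariate and 0.121 without it, and the share was not counted after median centring. A single control is argued against too, with 87.5% as the lowest share when each was left out. A treatment effect on many genes remains open.

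MHC class II levels differed between samples of a group, as in CRT with means of 7.317, 6.629 and 5.097. The means followed the sample numbers, with 6.49 to 7.317 in samples 1 to 5 and 5.097 to 6.239 in samples 6 to 12. Nontreated, SRT and CRT hold samples on both sides of this division. A batch along the numbers may be a source and was not tested for MHC class II. Depth is argued against as the whole cause, since r with the log2 scale step was -0.314 and a range of 1.867 was left after that trend was removed. Carried-over cells, which the sort for CD8 would remove, may be a source, but the mean of 5 macrophage and monocyte probes gave r = 0.24 (permutation p = 0.45, adjusted 0.56, rho = 0.245 with p = 0.44), and -0.202 without the 2 farthest samples, which leaves it open. This test was first tried with Il1b (r = 0.832), a gene chosen after its values were seen, and was then replaced by the wider list. A change of MHC class II in the T cells themselves was not tested.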

How the results depend on the processing

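The settings voom, background subtraction, probes above background, the scale step and the number-run block were chosen after the data were seen, and the others were planned. Of the alternative values of counts, list tests and correlations, 346 kept their direction and stayed on their side of the threshold or within 1.5 times, 112 moved and 9 became weaker. Of those of single genes 2345 were the same, 204 weaker, 26 stronger and 56 reversed. Where not stated otherwise, the cause was not tested. No paired analysis was possible because the groups share no sample numbers in the labels. The planned edgeR test was not run, because the values are deposited as logs and the recovered counts are not the deposited unit, and voom took its place. Pseudocounts did not apply, and scaling on reference genes was not run because 0 of 42 were measured. Depth limits the low probes: Nontreated replicate 3, with 118694 counts, had a background of 15.1 against 6.24 in replicate 1.

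Counts of probes past the threshold moved as follows. With median centring, CRT against Nontreated had 12 (11 up), SRT-like 0, radiotherapy as a whole 11 (10 up) and the F test 1. With quantile normalization these were 13 (11 up), 0, 2 and 1. The floor on mean log2 gave SRT 5, SRT-like 9 and the F test 25, and leaving out the lowest 25% of probes gave SRT-like 9 and the F test 16, both testing fewer probes. A trended robust prior gave SRT 4, SRT-like 8 and the F test 23. Sample weights gave CRT 62, SRT-like 15, radiotherapy as a whole 64 and the F test 11. Voom gave SRT 2, SRT-like 15 and the F test 25, and background subtraction SRT-like 0. Probes above background gave SRT 3, SRT-like 9 and the F test 19. The scale step as a covariate gave SRT-like 13 and the F test 2, and the block SRT 3. With only the 6 samples compared, CRT and SRT-like had 0, with fewer residual degrees of freedom, and the 9 irradiated samples as 1 group gave 8.

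Leaving out 1 sample at a time gave 0 to 1 for SRT (1 without Nontreated replicate 1), 0 to 58 for CRT, 0 to 9 for SRT-like, 0 to 1 for SRT-like against CRT, 2 to 77 for radiotherapy as a whole and 0 to 6 for the F test. CRT had 0 without CRT replicate 2, 6 without CRT replicate 3, 3 without Nontreated replicate 1, 15 without Nontreated replicate 2 and 58 without Nontreated replicate 3. SRT-like had 9 without SRT replicate 3, 3 without Nontreated replicate 1, 1 without SRT-like replicate 1 and 0 without each of the other 9 samples. SRT-like against CRT had 1 without Nontreated replicate 2. Radiotherapy as a whole had 77 without Nontreated replicate 3, 4 without Nontreated replicate 1, 9 without Nontreated replicate 2, 14 without CRT replicate 1, 15 without SRT-like replicate 3 and 2 without CRT replicate 2 or SRT-like replicate 2. The F test had 6 without SRT replicate 3 and 1 without Nontreated replicate 1.

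Counts of lists past camera's threshold were 1 in SRT, 1 in CRT and 3 in SRT-like against Nontreated, 2 in SRT against CRT, 10 in SRT against SRT-like, 9 in SRT-like against CRT and 2 for radiotherapy as a whole. With an estimated correlation they were 0 in all 7. Fry gave 0 in SRT, 4 in CRT, 6 in SRT-like, 0 in SRT against CRT, 0 in SRT against SRT-like and 1 in SRT-like against CRT. Median centring gave 4 in SRT. The floor gave 3 in CRT, 4 in SRT against SRT-like and 4 in SRT-like against CRT. Voom gave 3 in SRT and 2 in CRT. Background subtraction gave 2 in SRT, 3 in CRT and 4 in SRT-like against CRT, and probes above background 5 in each of the contrasts of SRT-like with SRT and CRT. The scale step gave 2 in CRT, 5 in SRT against SRT-like and 5 in SRT-like against CRT, and the block 2 in SRT.

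Without 1 sample at a time, lists ranged from 1 to 8 in SRT (8 without Nontreated replicate 3, 2 without Nontreated replicate 1 or CRT replicate 3, 3 without SRT replicate 2). They ranged from 1 to 6 in CRT (6 without Nontreated replicate 3, 4 without CRT replicate 3, 2 without Nontreated replicate 2, CRT replicate 2, SRT-like replicate 2 or SRT-like replicate 3). They ranged from 1 to 5 in SRT-like (5 without Nontreated replicate 1 or 2, 1 without Nontreated replicate 3) and from 1 to 4 in SRT against CRT (1 without SRT replicate 3, 4 without CRT replicate 1). In SRT against SRT-like they ranged from 4 to 10 (4 without SRT-like replicate 1, 6 without SRT replicate 1, 5 without SRT replicate 2).

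The interferon list lost its call with an estimated correlation, its medians staying at 1.312 in SRT, 2.151 in CRT, 1.496 in SRT-like, 1.698 for radiotherapy as a whole, -0.814 in SRT against CRT and -0.737 in SRT-like against CRT, with adjusted p of 0.721, 0.246, 0.292, 0.332, 0.572 and 0.505. By fry it lost it in SRT (0.0655), SRT against CRT (0.227) and SRT-like against CRT (0.255). In the other settings run, each sample left out in turn included, it stayed past the threshold, with medians of 0.976 to 1.586 in SRT, 1.827 to 2.47 in CRT, 1.146 to 1.684 in SRT-like, 1.376 to 1.809 for radiotherapy as a whole, -1.114 to -0.702 in SRT against CRT and -0.948 to -0.474 in SRT-like against CRT.

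Correlations between modes were higher with the floor, at 0.743 for SRT and SRT-like and 0.636 for CRT and SRT-like. Without 1 Nontreated sample at a time they ranged from 0.676 to 0.8 for SRT and CRT, 0.617 to 0.742 for SRT and SRT-like and 0.549 to 0.687 for CRT and SRT-like, the highest each time without Nontreated replicate 3.

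Fixed genes near 0 changed sign, none of them past the threshold. In SRT against Nontreated, median centring gave Ifng -0.248, Prf1 -0.085 and Slamf6 -0.107, quantile normalization Slamf6 -0.068, and sample weights Havcr2 0.053, Ifng -0.31 and Pdcd1 0.001. In CRT against Nontreated median centring gave Ifng -0.076. In SRT-like against Nontreated Prf1 was -0.121 with median centring and -0.061 with quantile normalization. In SRT against CRT Tnfrsf9 was 0.045 with median centring, 0.144 with quantile normalization, 0.051 with weights and 0.042 with the scale step, and Ifng 0.029 with quantile normalization. In SRT against SRT-like Prf1 was -0.008 with weights, Tnfrsf9 0.175 with quantile normalization, and Tox -0.084 with median centring and -0.019 with background subtraction. In SRT-like against CRT Havcr2 was 0.098 with median centring and Tnfrsf9 -0.031 with quantile normalization. For radiotherapy as a whole median centring gave Havcr2 -0.047, Ifng -0.03 and Prf1 -0.044, and weights Pdcd1 0.053. These signs follow the median shift in part, since centring removes it.

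Leaving out 1 sample at a time, the ranges that crossed 0 were as follows. In SRT against Nontreated they were -0.188 to 0.071 for Havcr2, -0.275 to 0.36 for Ifng, -0.312 to 0.018 for Pdcd1 and -0.005 to 0.313 for Slamf6. In SRT-like against Nontreated they were -0.237 to 0.033 for Slamf6 and -0.209 to 0.021 for Tnfrsf9. In SRT against CRT they were -0.523 to 0.112 for Ifng, -0.029 to 0.294 for Pdcd1, -0.39 to 0.013 for Prf1 and -0.129 to 0.168 for Tnfrsf9. In SRT against SRT-like Tox ran from -0.105 to 0.202. In SRT-like against CRT they were -0.124 to 0.054 for Havcr2, -0.029 to 0.413 for Ifng and -0.075 to 0.196 for Slamf6. For radiotherapy as a whole they were -0.188 to 0.093 for Pdcd1 and -0.098 to 0.034 for Slamf6.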

Other observations

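The comparisons of this part were all chosen after the values were seen, and none was planned.

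Granzymes C to G and N, serine proteases encoded side by side in 1 cluster, were set together as 6 probes. Their mean difference from Nontreated was 1.00 ± 0.32 (SE) in SRT (adjusted p = 0.0227 by limma's fry, over the 7 contrasts), 0.37 in CRT (0.252) and 0.98 in SRT-like (0.0227), and 0.78 ± 0.26 over the modes (0.0227). The hypothesis that the cluster may be induced more in SRT than in CRT was tested directly and stays open, with a difference of 0.62 ± 0.32 and an adjusted p of 0.148 by limma's fry. Gzmn and Gzmg were not above background in every sample of any group. The 4 other probes alone gave 0.93 ± 0.27 in SRT (adjusted p = 0.0187), 0.39 in CRT (0.23), 0.96 in SRT-like (0.0187) and 0.54 ± 0.27 between SRT and CRT (0.115), all by limma's fry. Granzyme probes could share RNA of close relatives.

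Across the 12 samples the MHC class II mean was related to 5 other measures, with 100000 permutations and adjustment over the 5. The inflammatory cytokine gene Il1b gave Pearson's r = 0.832 (p = 0.00092, adjusted 0.0046) and Spearman's rho = 0.832 (p = 0.0011, adjusted 0.0055), with r = 0.756 without the 2 farthest samples and 0.832 within groups. Ccl22 gave r = 0.738 (p = 0.0064, adjusted 0.016) and rho = 0.748 (p = 0.0066, adjusted 0.016), with 0.566 without those samples and 0.704 within groups. The T cell markers gave r = 0.283 (p = 0.37, adjusted 0.56) and rho = 0.259 (p = 0.42, adjusted 0.55), with r = 0.231 without those samples and 0.554 within groups. The interferon mean gave r = -0.087 (p = 0.79, adjusted 0.79) and rho = 0.035 (p = 0.92, adjusted 0.92), with -0.278 and -0.515. The relation to macrophage probes is given above, and r within groups was -0.008. The values within groups were not tested. Il1b lay between 5.234 and 6.525 in samples 1 to 5 and between 3.812 and 4.827 in samples 6 to 12. MHC class II was divided in the same way. The permutations treat all samples as exchangeable, so the relation to Il1b may reflect this division. The values within groups do not remove it, because Nontreated, SRT and CRT hold samples on both sides.

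With the MHC class II mean as a covariate, the difference between SRT-like and CRT was 2.35 ± 0.54 (SE) for Itgae and 2.02 ± 0.40 for Zfp683, with adjusted p of 0.233 and 0.222 by limma, against 2.19 and 1.83 without it. Neither passed in either fit, and both probes were above background in only 1 of the 3 CRT samples.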
